A study of Mus musculus with 14 samples.

How the data were processed

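Expression was measured in CD8 T cells of Suv39h1-KO mice and WT littermates, naive or Kb-OVA+ on day 7 after infection, isolated by flow cytometry. Per the labels' protocols, RNA was extracted with an RNeasy Micro kit with DNase treatment on the column, and cDNA was made by the standard Affymetrix protocol for the GeneTitan device. Per the submitters' processing notes, R 3.1.0, RMA and the oligo package were used. The order and settings of these steps and the genome build are not given in the sources used here. The values deposited by the authors are on the log2 scale, as RMA gives them after background correction, quantile normalization between arrays and summary per probe set. Their scale was checked from the values, with array medians of 3.497 to 3.678 and nearly equal means. Genes were not centred.

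The value table held 41345 probe sets on 14 arrays. The platform's probe table gave exactly 1 gene for 23521 probe sets and several genes for 1814, and did not list 16010, which are unnamed here. Of the probe sets with 1 gene, 23328 matched a RefSeq gene (GRCm38.p6 table, used only for names and for which genes neighbour each other) through the Entrez number, and 0 symbols changed. No gene was named from a probe set with several genes. For the 1082 genes with several probe sets, the one with the highest mean over all arrays was used, which left 22180 genes. No coordinates are given, since the authors' build is not stated. No filter on dim genes was applied.

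Groups came from the sample titles. The 2 technical arrays of naive replicate 1 of each genotype were averaged and counted as 1 mouse. They correlated at 0.946 (WT) and 0.935 (KO), and their median absolute log2 difference was 0.234 and 0.251, against 0.22 and 0.204 between naive replicates 2 and 3. Differences were tested with limma 3.58.1 in R 4.3.3. The 4 group means of all 12 mice were fitted in 1 model (lmFit, contrasts.fit, eBayes), with 8 residual degrees of freedom, and 2-sided p-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. The contrasts were KO minus WT in naive cells, KO minus WT in activated cells, activated minus naive in each genotype, and the interaction. No array was shared between the pairs of contrasts whose overlap is given. The activation contrasts of WT and KO cells hold the array sets described below in the same unequal shares, so they are not independent in that respect. Of 22 gene lists, each was tested against the other genes with camera at a preset correlation of 0.01, adjusted over the lists of a contrast. camera with a correlation estimated per list was an alternative, and fry another that tests each list against no change and not against the other genes, and members were also adjusted over the list alone.

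The lists were H3K9 methylation and heterochromatin machinery, naive and stem-like CD8 T cell genes, memory-associated genes, effector genes, NK-type receptors, inhibitory receptors and exhaustion genes, other helper-lineage genes, survival and apoptosis genes, cell cycle genes, interferon-stimulated genes, glycolysis genes, immediate-early genes, germline genes, genes next to Suv39h1 on chromosome X, sex genes, lymphoid housekeeping and CD8 T cell identity, and markers of B cells, CD4 T cells, NK cells, myeloid cells, neutrophils, and red cells and platelets. Members without a probe set of their own, such as Tcf7, Zeb2 and Cd74, were not analysed here. The tests, lists, alternatives and the rule for named genes were fixed before the data were examined, apart from those stated below to be chosen later. By that rule, each contrast names up to 6 rising and 6 falling called genes of largest log2 fold change whose mice do not overlap and whose highest group mean is above 3.58, the median of all probe sets, with open places filled by genes of smallest p given as values. It adds up to 4 leading members of each list and always Ccr7, Il7r, Klrg1, Gzmb, Ifng, Tbx21, Eomes, Prdm1 and Pdcd1. Predicted genes, microRNA and small nucleolar RNA genes, receptor segments and sex-linked genes are counted but not named by it. Further list members that the text names, such as Bcl2, Bach2, Cd83 and Cxcr5, were chosen after their values were seen.

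To compare genes that fall or rise with activation without choosing and measuring them on the same arrays, lists of 200 genes were made from WT naive mice and 1 WT activated mouse, and measured on the other 2 WT activated mice and the 3 KO mice. Percentiles come from 10000 random lists matched on mean expression.

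Replicate numbers occur in all groups. Deviations of same-numbered naive mice of the 2 genotypes from their group means correlated at 0.47, 0.17 and 0.12 for replicates 1, 2 and 3 (highest with another number -0.26, 0.23 and 0.13). All were above 0.1, but replicates 2 and 3 correlated more with another number. Of the naive mice, replicate 1 alone lies in the first array set, so the numbers follow the sets. Pairs were thus not established, from the data or from the labels, and the main model used none. In the other pairs of groups not all same-numbered correlations were above 0.1.

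Alternatives were the replicate number as a block, only the groups compared, trended and robust eBayes, dim genes left out, quantile normalization, median centring, each technical array alone, the mean of a gene's probe sets, all probe sets, array weights, a 1.5-fold threshold, and each mouse left out in turn. Chosen after seeing the data were the array set as a block and each set alone. The methods were tested on simulated data with shifts in 200 of 22180 genes. For KO minus WT in activated cells, 5.07% of genes shifted by 0.5 log2 were called, 55.1% of those shifted by 1 and 92% of those shifted by 2, and 5.2% of calls were false. The corresponding shares for naive cells were 5.37%, 54% and 93.5%, and for the interaction 0.746%, 16.3% and 74.2%. camera called 20 of 22 lists shifted by 0.5 and 0 of 452 unshifted lists, with genes simulated as independent. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.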

Results

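Gene expression was measured on Affymetrix GeneTitan arrays in CD8 T cells of Suv39h1-knockout (KO) mice and their wild-type (WT) littermates. Suv39h1 encodes a histone methyltransferase that places trimethylation on lysine 9 of histone H3, a mark of silent chromatin. Naive cells and activated cells were sorted from each genotype. The activated cells were Kb-OVA+ cells, which recognise an ovalbumin peptide on the MHC molecule Kb, taken 7 days after infection with Listeria monocytogenes that expresses ovalbumin. Each of the 4 groups held 3 mice, and replicate 1 of both naive groups was run on 2 arrays that were averaged, so that 14 arrays gave values for 12 mice. Values were deposited log2 RMA values with array medians of 3.50 to 3.68, and 22180 genes were tested. The first principal component (24.1% of the variance) separated naive from activated cells. The second (18.2%) parted the arrays into 2 sets that each held all 4 groups. The first set held naive replicate 1 and activated replicates 1 and 2 of each genotype, and the second set held naive replicates 2 and 3 and activated replicate 3. The labels do not name these sets, so values within each set are given beside the main gene counts and the leading list results. Signal over background was not tested, so the size of a difference is uncertain wherever a group mean lay below 3.58, the median of all probe sets. The number of arrays limits the precision, with a median standard error (SE) of 0.195 log2 for a difference between 2 groups.

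The targeted gene, Suv39h1, was not analysed here, since no probe set was assigned to it alone, and the genotype labels could not be checked by its level. Of the 23 measured genes next to it on chromosome X, none was called between genotypes in either state, and the list's median difference was 0.02 log2 in naive cells (adjusted p = 0.96) and -0.06 in activated cells (mean 0.02, adjusted p = 0.843). The exception by size was Pim2, a serine/threonine kinase gene of that list, which was 0.95 ± 0.16 log2 (SE) higher in activated KO than activated WT cells (adjusted p = 0.129) and was the 1 member called when adjusted over the list alone. Other enzymes and readers of H3K9 methylation, 17 measured genes, had a median difference of -0.05 in naive cells (adjusted p = 0.95) and -0.05 in activated cells (mean 0.03, adjusted p = 0.747). Setdb1, another H3K9 methyltransferase, was 0.45 ± 0.18 higher in activated KO cells, and Setdb2 0.54 ± 0.19 higher, without passing the test. Y-linked Eif2s3y lay between 6.96 and 8.63 and Xist between 2.77 and 3.81 in the 12 mice. Among the 4 measured sex genes none was called, and the list's median genotype difference was -0.31 in naive cells (adjusted p = 0.96) and 0.08 in activated cells (adjusted p = 0.828). Eif2s3y and Kdm5d were lowest in KO naive replicate 1, at 6.96 and 5.65. Genes of CD8 T cell identity and housekeeping, such as Cd8a and Cd3e, had medians of 0.01 and -0.01 between genotypes (adjusted p = 0.97 and 0.977).

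The first comparison asked what changed from naive to day 7 antigen-specific cells in WT mice. Among the genes that the rule names, the linker histone gene H1f5 rose by 8.44 ± 0.20 log2 (SE, n = 3 mice per group), Gzmb, encoding granzyme B, by 7.86 ± 0.21, S100a6 by 7.54 ± 0.61, the effector marker Klrg1 by 7.05 ± 0.18, Gzmk by 6.86 ± 0.13 and Klrc1, which encodes the receptor NKG2A, by 6.54 ± 0.23. Tmem108 fell by 5.28 ± 0.67, Slc16a5 by 4.54 ± 0.48, Rflnb by 4.41 ± 0.24, the integrin gene Itgae by 4.37 ± 0.28, Dapl1 by 3.78 ± 0.26 and the interferon-inducible GTPase gene Iigp1 by 3.58 ± 0.39. All of these rises except that of S100a6 are of uncertain size, since H1f5, Gzmb, Klrg1, Gzmk and Klrc1 lay at 3.08, 3.15, 2.55, 3.38 and 3.32 in naive WT cells, as is the fall of Iigp1, which lay below the median of all probe sets in activated WT cells. In all, limma called 872 genes higher and 871 lower at a Benjamini-Hochberg adjusted p under 0.05.

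Gene lists of T cell states changed in WT cells as follows. Of 26 effector genes 25 rose and 1 did not pass the test, with a list median of 4.45 (camera adjusted p = 1.19e-56). They included Tbx21, the transcription factor gene for T-bet (4.40 ± 0.20), and Ifng (1.55 ± 0.22). All 30 cell cycle genes rose, with a median of 3.11 (adjusted p = 5.1e-59), among them Mki67 at 5.59 ± 0.15 and Ccnb2 at 5.35 ± 0.20. Of 21 naive and stem-like genes 17 fell and 4 did not pass, with a median of -2.02 (adjusted p = 2.57e-24). Ccr7, the receptor for entry into lymph nodes, fell by 3.43 ± 0.39, Igfbp4 by 3.54 ± 0.27 and Il7r, the IL-7 receptor gene, by 2.04 ± 0.33. The naive and stem-like list had medians of -2.08 and -2.05 within the first and the second set, the effector list 4.26 and 4.54, and the cell cycle list 3.36 and 3.48. When adjusted over the list alone, 25 effector genes and 30 cell cycle genes rose and 20 stem-like genes fell.

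Receptor lists moved with activation too. Of 14 inhibitory receptor and exhaustion genes 6 rose, 2 fell and 6 did not pass (median 0.57, adjusted p = 0.000131), with Havcr2 up by 4.51 ± 0.24, Tigit by 3.66 ± 0.31, Lag3 by 3.24 ± 0.18 and Pdcd1 by 2.02 ± 0.50. Pdcd1 was at 5.85, 4.88 and 7.39 in the 3 activated mice and differed by 1.34 without replicate 3 (adjusted p = 0.0527). The rises of Havcr2 and Lag3 are of uncertain size, with naive WT levels of 2.81 and 3.45. The call of Pdcd1 was also lost without any 1 WT naive mouse or WT activated replicate 1 (adjusted p 0.0559 to 0.091) and within the first set (adjusted p = 0.287). Of 12 NK-type receptors 4 rose (median 0.52, adjusted p = 3.55e-08), among them Klrk1, which encodes NKG2D, by 4.30 ± 0.37. Among 7 NK cell markers Eomes and Itga2, the latter from 3.20 and so of uncertain size, rose (median 1.34, adjusted p = 2.85e-05), and Eomes is also a T cell transcription factor gene. These 3 receptor and NK lists and the effector, cell cycle and stem-like lists were the 6 lists called in WT cells that held with an estimated correlation. When adjusted over the list alone, 7 inhibitory receptor genes rose and 2 fell, and 4 NK-type receptors and 3 NK cell markers rose.

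Other WT list calls did not hold that way. Memory-associated genes went both ways, with 4 higher, such as Cxcr3 (3.66 ± 0.25) and Cd44 (2.48 ± 0.24), and 3 lower, such as Tnfsf8 (-3.18 ± 0.32) and Socs3 (-2.53 ± 0.30). Their median was 0.42 (adjusted p = 0.02, and adjusted p = 0.0894 with an estimated correlation). Of 24 interferon-stimulated genes 9 fell and 1 rose (median -0.61, adjusted p = 1.76e-06, and adjusted p = 0.169 with an estimated correlation), with Ifit1 down by 3.01 ± 0.52. Of 13 glycolysis genes 4 rose, led by Pfkp at 1.38 ± 0.16 (median 0.51, adjusted p = 9.38e-07, and adjusted p = 0.055 with an estimated correlation). Of 18 immediate-early genes 5 fell, such as Egr3 by 2.42 ± 0.34, and Ier3 rose by 1.09 ± 0.25, a call lost without WT naive replicate 1 or 3 or WT activated replicate 3 (median -0.35, adjusted p = 0.00439, and adjusted p = 0.169 with an estimated correlation). Of 14 survival and apoptosis genes 3 rose: Birc5 (5.34 ± 0.37, of uncertain size from 2.99), also a mitotic gene, Bcl2a1a (2.10 ± 0.24) and Bak1 (1.24 ± 0.17). That list had a median of 0.12 (adjusted p = 0.0263, and adjusted p = 0.169 with an estimated correlation). When adjusted over the list alone, 6 memory-associated genes rose and 3 fell, 11 interferon-stimulated genes fell and 1 rose, 8 glycolysis genes rose, 6 immediate-early genes fell and 1 rose, and 4 survival genes rose and 1 fell.

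Of the marker lists of other blood cells apart from NK cells, B cell and neutrophil markers were called in WT cells by camera, and neither call held with an estimated correlation. B cell markers had a median of 0.62 with 12 of 14 above 0 (adjusted p = 0.00688, and adjusted p = 0.429 with an estimated correlation), and Ighm, which was already at 10.23 in naive WT cells, fell by 1.41 ± 0.19, but was 0.25 higher with the mean of its probe sets (adjusted p = 0.55). Neutrophil markers had a median of 0.50 with 11 of 11 above 0 and none called singly (adjusted p = 0.00236, and adjusted p = 0.377 with an estimated correlation). Myeloid markers (median 0.50, adjusted p = 0.0784), CD4 T cell markers (0.33, adjusted p = 0.265) and red cell and platelet markers (0.24, adjusted p = 0.621) did not pass. Nor did 15 other helper-lineage genes (median -0.06, mean 0.02, adjusted p = 0.899) and 14 germline genes (median 0.03, mean -0.03, adjusted p = 0.899). The WT count was 2294 with the array set as a block, and 912 and 922 within the first and the second set, where fewer mice enter.

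The second comparison asked the same of KO cells. H1f5 rose by 8.52 ± 0.20, Gzmb by 7.92 ± 0.21, the granzyme A gene Gzma by 6.81 ± 0.30, S100a6 by 6.64 ± 0.61, Klrg1 by 6.55 ± 0.18 and Klrc1 by 6.48 ± 0.23. Itgae fell by 3.74 ± 0.28, Igfbp4 by 3.61 ± 0.27, Tmem108 by 3.58 ± 0.67, the interferon-gamma receptor gene Ifngr2 by 3.07 ± 0.29, Dapl1 by 2.92 ± 0.26 and Rflnb by 2.90 ± 0.24. The rises of H1f5, Gzmb and Klrg1 are of uncertain size here too, with naive KO levels of 2.87, 3.23 and 2.54. limma called 801 genes higher and 456 lower. Of these, 641 of the higher genes were also called higher in WT cells (31.5 for independent lists) and 338 of the lower genes were called lower in both (17.9 for independent lists), with none called in opposite directions. The fold changes of all genes had a Pearson r of 0.836 and a Spearman rho of 0.552 between genotypes, across genes, which are not independent replicates. In both genotypes the naive group held more mice of the second array set and the activated group more of the first. The main model does not include the set. A difference between the sets can thus enter the folds and calls of both contrasts alike and add to their overlap and correlation. The lower overlap was 214 without KO naive replicate 2 and 207 without KO naive replicate 3.

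In KO cells 25 of 26 effector genes (median 3.93, adjusted p = 1.32e-64) and 29 of 30 cell cycle genes (median 3.01, adjusted p = 1.32e-64) rose. Of the 21 naive and stem-like genes 14 fell and 7 did not pass (median -1.2, adjusted p = 8.84e-18). Ccr7 fell by 2.39 ± 0.39 and Ccr9 by 2.13 ± 0.28, while Il7r differed by -0.35 ± 0.33 and did not pass (adjusted p = 0.694). This list had medians of -0.86 and -1.44 within the first and the second set. Memory-associated genes rose as a list (median 0.76, 7 higher and 2 lower, adjusted p = 2.88e-05), with Cxcr3 at 3.99 ± 0.25 and Cxcr5, a follicular homing receptor gene, at 1.88 ± 0.34. Tigit rose by 4.74 ± 0.31 and Havcr2 by 4.31 ± 0.24 in the inhibitory receptor list (median 0.92, adjusted p = 1.92e-07), and Klrc2 by 3.47 ± 0.21 among NK-type receptors (median 0.94, adjusted p = 7.74e-12). The rises of Tigit, Havcr2 and Klrc2 are of uncertain size, with naive KO levels of 3.42, 2.66 and 2.99. These 5 T cell lists beside the cell cycle list held with an estimated correlation, as did glycolysis genes (median 0.58, adjusted p = 5.54e-08), survival and apoptosis genes (0.25, adjusted p = 0.00065) and NK cell markers (1.56, adjusted p = 5.38e-07). When adjusted over the list alone, 26 effector genes, 30 cell cycle genes and 9 memory-associated genes rose, 2 memory-associated and 17 stem-like genes fell, and 9 inhibitory receptor genes rose and 1 fell.

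In the activated KO samples 8 of 14 B cell markers rose, among them the MHC class II genes H2-Aa by 3.37 ± 0.57 and H2-Ab1 by 3.35 ± 0.59, Cd79a by 2.41 ± 0.38 and Ms4a1, the CD20 gene, by 1.95 ± 0.42 (median 1.29, adjusted p = 9.64e-10, and adjusted p = 0.0819 with an estimated correlation). The call of Ms4a1 was lost without KO naive replicate 1 or 2 or KO activated replicate 2 or 3 (adjusted p 0.0546 to 0.0643). Ms4a1 lay at 2.88 and the neutrophil marker Lcn2 at 3.26 in naive KO cells, so the sizes of their rises are uncertain. Neutrophil markers S100a9 (3.05 ± 0.72) and Lcn2 (1.78 ± 0.26) rose as well, S100a9 with a call lost without KO naive replicate 1 or 2 or any 1 activated KO mouse (list median 0.77, adjusted p = 2.66e-06, and adjusted p = 0.144 with an estimated correlation). Myeloid markers had a median of 0.88 (adjusted p = 0.00175, and adjusted p = 0.278 with an estimated correlation), which was 0.16 within the first and 1.64 within the second set. H3K9 machinery genes had a median of 0.26 (adjusted p = 0.00129, and adjusted p = 0.117 with an estimated correlation), with Uhrf1, which also belongs to DNA replication, up by 3.81 ± 0.24. Interferon-stimulated genes (median -0.69, adjusted p = 3.23e-05, and adjusted p = 0.204 with an estimated correlation) and immediate-early genes (median -0.28, adjusted p = 0.0153, and adjusted p = 0.204 with an estimated correlation) fell as lists. When adjusted over the list alone, 12 B cell markers rose and 1 fell, and 5 neutrophil markers rose. The KO count was 1785 with the array set as a block, and 622 and 849 within the first and the second set.

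In naive cells limma called 2 genes between the genotypes, both higher in KO cells and both outside the rule for named genes, so that they were chosen after their values were seen. Gm7609, a predicted gene, was at 3.78 in WT and 7.55 in KO cells (3.77 ± 0.45 log2, adjusted p = 0.0452), and the microRNA gene Mir1932 at 3.46 and 5.64 (2.18 ± 0.27, adjusted p = 0.0452). Some probe sets carry the names of both Gm7609 and Csprs, so the values of either gene are uncertain. The WT level of Mir1932 lay below 3.58, the median of all probe sets, so the size of its difference is uncertain too. Gm7609 was 3.98 and 3.66 higher within the first and the second set, and Mir1932 2.25 and 2.15. With the replicate number as a block 1 gene was called, and leaving out any 1 of the 6 naive mice left 0 calls by limma, against 652 genes at an unadjusted p under 0.05 with all mice (1109 by chance).

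The 12 genes that the rule names by smallest p in naive cells did not pass. Atp11a, a phospholipid flippase gene, was at -1.09 ± 0.19 (adjusted p = 0.27), Tent5a at -1.23 ± 0.25 and Tmie at -1.18 ± 0.24 (both adjusted p = 0.71). At adjusted p = 1 followed B3gnt3 at -1.14 ± 0.25, Atf6 at 1.00 ± 0.22, Ctrl at 1.24 ± 0.28, Ramp3 at -0.59 ± 0.14, Dhrs1 at -0.99 ± 0.23, Rbm3os at -0.83 ± 0.20, the DNA sensor gene Aim2 at -1.14 ± 0.28, Arhgap29 at 0.97 ± 0.24 and App at -1.0 ± 0.25. B3gnt3, Rbm3os and App in KO and Arhgap29 in WT naive cells lay below the median of all probe sets. Il7r differed by -0.27 ± 0.33, Ccr7 by -0.02 ± 0.39, Tbx21 by 0.04 ± 0.20 and Eomes by 0.32 ± 0.22. No gene list was called by camera, by camera with an estimated correlation or by fry. The naive and stem-like list had a median of -0.02 (21 genes, adjusted p = 0.986) and levels of 8.67 ± 0.03 in WT and 8.65 ± 0.02 in KO cells (mean ± SD, n = 3). Median, mean and test differed in sign for this list and the cell cycle, germline, myeloid, and red cell and platelet lists. Interferon-stimulated genes had the lowest list median apart from the sex genes, at -0.12 (adjusted p = 0.541), and CD4 T cell markers the highest, at 0.14 (adjusted p = 0.541), with Tnfrsf4 at 0.67 ± 0.18. Tnfrsf4 was the only list member called when adjusted over the list alone.

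The comparison of activated KO with activated WT cells, the genotype effect after infection, called Gm7609 again. It was at 3.49 in WT and 8.09 in KO cells (4.60 ± 0.45, adjusted p = 0.00626), and 4.23 and 5.34 higher within the first and the second set. Its WT levels lay near 3.58, the median of all probe sets, and signal over background was not tested, so the size of its difference is uncertain. It was called in both states, and a difference between the mice in chromosome segment or gene copies at Gm7609 was not excluded. LOC100039029, chosen after its values were seen, was 2.05 ± 0.29 higher in naive (adjusted p = 0.104) and 1.88 ± 0.29 higher in activated KO cells (adjusted p = 0.103). It was not shown to be independent of Gm7609, since the probes of Gm7609, Csprs and LOC100039029 were not compared here. 5730507C01Rik, chosen in the same way, was 2.93 ± 0.45 (adjusted p = 0.121) and 2.24 ± 0.45 higher (adjusted p = 0.304), of uncertain size with WT levels of 2.74 and 3.18. In all, 1081 genes had an unadjusted p under 0.05 (1109 by chance), and genotype differences in naive and activated cells had a Pearson r of 0.0464 across genes.

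The genes that the rule names by smallest p missed the threshold. Among them Pik3ip1, an inhibitor of PI3 kinase, was 1.17 ± 0.16 higher in activated KO cells, Rnf43, an inhibitor of Wnt receptors, 1.25 ± 0.19 higher, the Notch-regulated gene Nrarp was at -0.96 ± 0.14 and Hip1 at -1.35 ± 0.20 (each adjusted p = 0.0924). The mTORC2 gene Prr5 was at -1.65 ± 0.26 (adjusted p = 0.103), the mitochondrial carbonic anhydrase gene Car5b at -1.21 ± 0.19 (adjusted p = 0.117), the ERK phosphatase gene Dusp6 at 1.26 ± 0.21 (adjusted p = 0.129) and Rflnb at 1.41 ± 0.24 (adjusted p = 0.135), followed by Bmpr2 at 0.94 ± 0.17 and Bambi-ps1 at 0.97 ± 0.18 (both adjusted p = 0.224), Bmpr2 from a WT level of 3.25. With the array set as a block 3 genes passed, Gm7609, Pik3ip1 (adjusted p = 0.016) and Il7r (adjusted p = 0.0305). Over all alternatives the adjusted p ranged from 0.016 to 0.662 for Pik3ip1 and from 0.0305 to 1 for Il7r. With the replicate number as a block 2 passed, and without KO activated replicate 2 the count was 0. In activated KO cells Pik3ip1, Nrarp, Hip1, Prr5, Car5b, Dusp6, Rflnb and Bambi-ps1 lay between activated and naive WT cells, while Rnf43 and Bmpr2 lay above both. Pik3ip1 was at 6.99 in naive WT, 4.97 in activated WT and 6.15 in activated KO cells, and Hip1 at 3.85, 7.07 and 5.71. These places do not point to 1 common share of naive cells within the activated KO samples. Nrarp lay at 4.36 in naive WT, 5.75 in activated WT and 4.785 in activated KO cells, nearer the naive level. Rflnb lay at 8.60, 4.19 and 5.59, nearer the activated level. Since these genes were picked by smallest p, naive cells were neither shown nor excluded as a part of these differences.

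The naive and stem-like list was higher in activated KO cells. Of its 21 measured genes 20 were above 0, with a median of 0.69 log2, and the list's mean level was 7.30 ± 0.28 in KO and 6.72 ± 0.07 in WT cells (SD, n = 3). None passed over all genes, and 7 passed when adjusted over the list alone. Il7r was at 9.81 in KO and 8.38 in WT cells (1.43 ± 0.33, adjusted p = 0.403), the survival gene Bcl2 differed by 1.07 ± 0.26 (adjusted p = 0.451), Satb1, a chromatin organiser gene, by 0.75 ± 0.17 (adjusted p = 0.387) and Ccr7 by 1.03 ± 0.39 (adjusted p = 1). Klf2 was the member below 0, at -0.22 ± 0.13. camera called the list (adjusted p = 9.31e-13), and the call held with an estimated correlation (adjusted p = 0.0303) and in fry, which tests against no change (adjusted p = 0.025). The list median was 0.56 within the first and 0.21 within the second set.

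**Figure D1:**
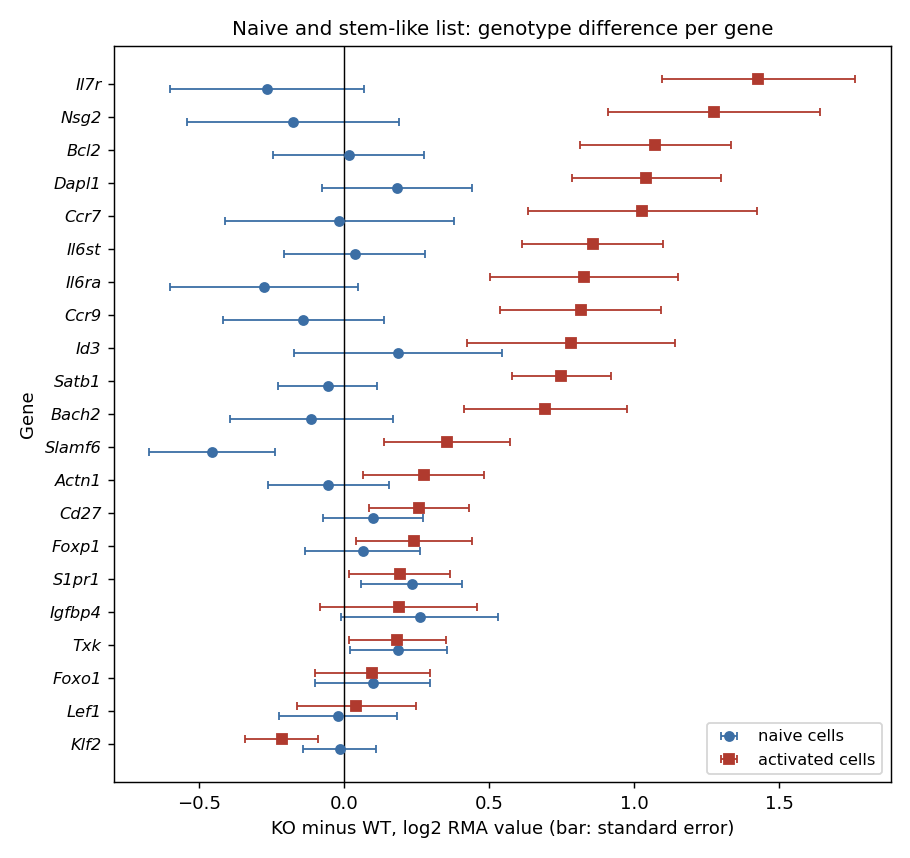
Difference between KO and WT cells in log2 RMA value (x axis) for each measured gene of the naive and stem-like list (y axis), in naive cells (blue circles) and activated cells (red squares), with bars for the standard error from limma (3 mice per group). In activated cells 20 of the 21 genes lie above 0, from Il7r at 1.43 down to Klf2 at -0.22, while the naive values have a median of -0.02.

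Memory-associated genes were also higher in activated KO cells, with a median of 0.31 and 11 of 15 above 0 (adjusted p = 8.32e-05, and adjusted p = 0.0303 with an estimated correlation). The list's level was 6.84 ± 0.03 in KO and 6.39 ± 0.04 in WT cells (SD, n = 3), and its median 0.21 within each set. No member passed over all genes and 4 passed when adjusted over the list alone. Tnfsf8, the CD30 ligand gene, differed by 1.57 ± 0.32 (adjusted p = 0.304), the cytokine signalling inhibitor gene Socs3 by 1.14 ± 0.30 and the chemokine receptor gene Cxcr5 by 1.26 ± 0.34 (both adjusted p = 0.707). Cxcr5, Cd83 and the stem-like genes Ccr7 and Bach2 are also expressed by B cells, whose markers were higher in the same samples. From activated replicate 1 to 2, both of the first array set, the B cell level rose in both genotypes. Cxcr5 did not rise with it (6.83 and 6.62 in KO, 5.09 and 4.95 in WT mice). Ccr7 rose in WT (6.13 and 6.94) but not in KO mice (7.71 and 7.65). Tnfsf8 lay at 7.37 in naive WT, 4.18 in activated WT and 5.75 in activated KO cells. Socs3 lay at 6.315 to 7.44, 3.97 to 4.80 and 5.28 to 6.07 in the mice of these groups. Activated KO cells thus lay between naive and activated WT cells for these genes, but not for Cxcr5. Naive cells within the activated KO samples were not tested as a source for this list. The NK-type receptor list was called (median 0.16, 9 of 12 above 0, adjusted p = 0.00817, and adjusted p = 0.0741 with an estimated correlation), with 2 members called when adjusted over the list alone. It was not called without WT activated replicate 3 (adjusted p = 0.208) or KO activated replicate 3 (adjusted p = 0.0904), nor within the first set (adjusted p = 0.52), and its median was 0.12 and 0.50 within the sets. Its leading gene Klra9, a Ly49 family receptor, was at 2.58 in WT and 4.37 in KO cells (1.79 ± 0.33, adjusted p = 0.224), of uncertain size at that WT level. The stem-like and memory-associated lists were the calls of this comparison that held with an estimated correlation.

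Effector genes as a list did not pass (26 genes, median -0.07, adjusted p = 0.305). Gzmb differed by 0.13 ± 0.21, Ifng by 0.25 ± 0.22, Tbx21 by -0.15 ± 0.20, Eomes by -0.15 ± 0.22, Prdm1 by -0.28 ± 0.34 and Pdcd1 by -0.06 ± 0.50 (each adjusted p = 1). The trafficking receptor genes S1pr5, at -1.42 ± 0.28 (adjusted p = 0.304), and Cx3cr1, at -1.44 ± 0.44 (adjusted p = 0.859), and the terminal effector marker Klrg1, at -0.51 ± 0.18 (adjusted p = 0.936), were lower without passing, and 1 effector gene passed when adjusted over the list alone. The cell cycle list was lower, with a median of -0.16 and 26 of 30 genes below 0 (adjusted p = 0.00824, and adjusted p = 0.658 with an estimated correlation). No cell cycle gene passed, also not when adjusted over the list alone, and the list was not called without WT activated replicate 3 (adjusted p = 0.623), KO activated replicate 1 (adjusted p = 0.0958) or KO activated replicate 2 (adjusted p = 0.375), nor within the second set (adjusted p = 0.373). Its median was -0.18 and -0.06 within the sets. Inhibitory receptors (median 0.11, adjusted p = 0.12), survival and apoptosis genes (0.03, adjusted p = 0.454), interferon-stimulated genes (0.06, adjusted p = 0.877), glycolysis genes (0.09, adjusted p = 0.747), immediate-early genes (0.07, adjusted p = 0.843), helper-lineage genes (-0.03, adjusted p = 0.876) and germline genes (-0.03, adjusted p = 0.619) did not pass.

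Of the lists of markers of other blood cells, B cell markers alone were called between the same activated samples, and that call did not hold with an estimated correlation. All 14 B cell markers were above 0, with a median of 0.67 (adjusted p = 5.82e-10, and adjusted p = 0.179 with an estimated correlation) and 0.47 and 1.28 within the first and the second set. H2-Ab1 differed by 1.41 ± 0.59, Cd79a by 1.05 ± 0.38 and Ighm by 0.85 ± 0.19, and 1 marker passed when adjusted over the list alone. Unlike H2-Ab1 and Cd79a, Ighm was higher in naive WT cells (10.16 to 10.33) than in activated KO cells (9.57 to 9.785). Its change with activation also depended on the probe sets used. B cells within the samples were not excluded. The B cell list was at 5.35, 6.06 and 6.55 in the 3 activated KO mice and 4.70, 5.69 and 5.39 in the activated WT mice. KO replicate 3, the mouse with the highest B cell level, had the lowest stem-like level (6.98, against 7.46 and 7.47). It was the only activated KO mouse of the second array set, and WT replicate 3 of that set was also lowest (6.64, against 6.77 and 6.77). Mouse and set cannot be told apart for replicate 3, so no conclusion on B cells is drawn from it. Replicates 1 and 2 both lie in the first set. Between them the B cell level went from 5.35 to 6.06 in KO and from 4.70 to 5.69 in WT mice. The stem-like level stayed at 7.46 and 7.47 in KO and at 6.77 in both WT mice. It thus did not follow the B cell level in these few mice. Neutrophil markers had a median of 0.42 (adjusted p = 0.0891), -0.07 and 1.09 within the sets, red cell and platelet markers 0.23 (adjusted p = 0.216), -0.01 and 1.2 within the sets, and myeloid markers 0.19 (adjusted p = 0.144), -0.02 and 0.57 within the sets. NK cell markers (median 0.24, adjusted p = 0.3) and CD4 T cell markers (median -0.06, mean 0.11, adjusted p = 0.619) did not pass. Tnfrsf4 (0.76 ± 0.18) among CD4 T cell markers and the platelet gene Pf4 (1.28 ± 0.39, from a WT level of 3.12) were called when adjusted over the list alone. Without KO activated replicate 3 camera called 4 lists in place of 5, and limma 1 gene.

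**Figure D2:**
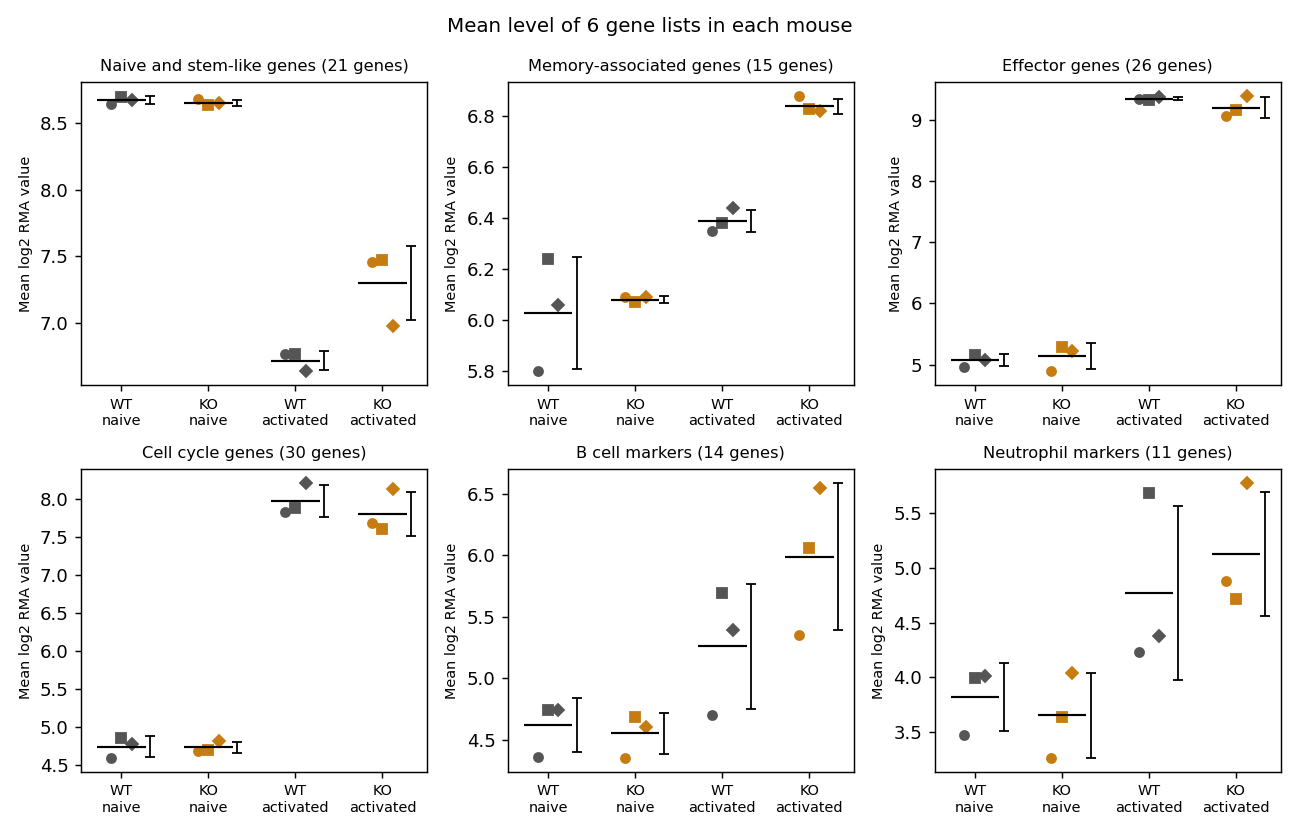
Mean log2 RMA value over the genes of 6 lists (y axes, 1 panel per list) in each mouse of the 4 groups (x axis). Circles, squares and diamonds mark replicates 1, 2 and 3, horizontal lines the mean and bars the SD of 3 mice, and each y axis has its own range. The stem-like level was 7.46, 7.47 and 6.98 in activated KO mice and 6.77, 6.77 and 6.64 in activated WT mice, and the B cell level 5.35, 6.06 and 6.55 against 4.70, 5.69 and 5.39.

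The interaction asked whether the genotype effect differed between the states. limma called 0 genes, with 820 at an unadjusted p under 0.05 (1109 by chance) and a median SE of 0.275. By smallest p the rule names Rap2a (-1.68 ± 0.31), Rab6b (1.37 ± 0.26), Bambi-ps1 (1.35 ± 0.26), Prr5 (-1.88 ± 0.36), Pik3ip1 (1.11 ± 0.23), Nrarp (-0.95 ± 0.20), Utp25 (1.17 ± 0.25), Hip1 (-1.33 ± 0.28), Zfp459 (2.00 ± 0.43), Dgkh (1.65 ± 0.36), Ppargc1b (1.12 ± 0.25) and Tmie (1.51 ± 0.33), and Il7r was at 1.70 ± 0.47 (each adjusted p = 0.999). Prr5 in naive cells and Dgkh in naive KO cells lay below the median of all probe sets. camera called 3 lists, and none of these calls held with an estimated correlation or in fry. The stem-like list had a median interaction of 0.81 with 16 of 21 genes above 0 (adjusted p = 1.16e-07, and adjusted p = 0.162 with an estimated correlation), 0.60 and 0.48 within the sets. Memory-associated genes had 0.28 (adjusted p = 0.0165, and adjusted p = 0.162 with an estimated correlation), 0.18 and 0.33 within the sets, with 2 members called when adjusted over the list alone. Its call was lost within the first set (adjusted p = 0.698). B cell markers had 0.77, with all 14 above 0 (adjusted p = 8.22e-07, and adjusted p = 0.494 with an estimated correlation), 0.52 and 1.28 within the sets. NK-type receptors had a median of -0.06 and a mean of 0.24 (adjusted p = 0.255), with Klra9 called when adjusted over the list alone, and germline, CD4 T cell and identity lists also differed in sign between median and mean.

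The last comparison asked whether genes that fall with activation in general were higher in activated KO cells. The 200 genes highest in naive over activated WT cells were chosen with 1 activated WT mouse and measured on the other mice. Their median KO minus WT difference was 0.15, 0.29 and 0.30 for lists made with WT activated replicates 1, 2 and 3, above all 10000 random lists matched on mean expression each time. The 200 genes highest in activated WT cells had medians of -0.22, -0.20 and -0.05, below all random lists. With 1 WT mouse left out, the array sets were not balanced between the genotypes. The WT mice measured were replicates 2 and 3, 1 and 3, or 1 and 2, and replicate 3 alone lies in the second set. The array set was not taken into account here or in the shares that follow, so its part in these values is not excluded. On the linear scale, activated KO cells differed from activated WT cells by 14.4%, 16.5% and 13.3% of the gap to naive WT cells (median over 15, 15 and 16 of the 21 stem-like members for the 3 choices, those at least 1 log2 lower in the chosen WT mouse than in naive cells) and by 4.94%, 8.85% and 9.25% (other naive-high genes), so that naive cells within the activated KO samples were not excluded. This limit on members was set when the script was written and not when the test was planned. These percentiles describe the lists in these mice and are no test across mice.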

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

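Chosen only after the data or results were seen were the tests by array set, of stem-like members that B cells lack, of a common naive share and of chromosome neighbours. The last was also amended after its result was seen, to require at least 10 genes called in both states for segments to be excluded, since 1 gene was called in both and a segment with 1 measured gene leaves no neighbours.

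The naive and stem-like list stood out because camera called its interaction of genotype and state, with a median of 0.805 log2 (adjusted p = 1.16e-07, 0.162 with an estimated correlation). Array sets are argued against as its whole cause by the design, since each held as many activated KO as WT mice and a common shift cancels. Within-set medians were 0.561 and 0.214, the latter from replicate 3 of each genotype alone. The set as a block cannot change this difference (camera adjusted p = 4.51e-14). The 6 members that mature B cells lack (Il7r, Dapl1, Lef1, Nsg2, Txk, Igfbp4) were on average 0.693 higher in KO cells (SE 0.256, 2.71 times the SE). That mean rests mostly on Il7r, the list's largest difference, Dapl1 and Nsg2. On the linear scale Lef1 (527.6 in WT and 562.2 in KO activated cells), Txk (174.3 and 198.5) and Igfbp4 (27.94 and 31.42) differed little. The test was set to argue against B cells where this mean lay above 0 by more than 2 SE. It does so for the members that carry the mean, Il7r, Dapl1 and Nsg2. In each of them all activated KO mice lay above all activated WT mice. B cells are not excluded for the other members of the list. Naive CD8 T cells carried into the activated KO samples stay open, although the Kb-OVA+ sort would remove them: the list's median share of the naive level lay at percentile 93.2 of random sets of naive-high genes (97.1, 93.8 and 88.8 for the 3 choices of WT mouse), within the middle 95% each time. A common share of 11.1% left 10 of 14 members within 2 SE, with Il7r 3, Bcl2 2.49 and Satb1 2.05 SE above it and Igfbp4 at -3.46, and 11.8% fitted other naive-high genes, with 315 of 349 within 2 SE. Both fits chose and measured genes on the same WT activated arrays, which can raise the share, so nothing is drawn from their closeness. On WT activated mice not used for the choice, the median shares were 14.4%, 16.5% and 13.3% for the list and 4.94%, 8.85% and 9.25% for the other genes. A change of the KO cells themselves was not tested apart from carried-over naive cells.

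B cell markers stood out in the same way, with a median interaction of 0.769 (adjusted p = 8.22e-07, 0.494 with an estimated correlation). Array sets are argued against as the whole cause by the design, since a shift common to a set cancels from activated KO minus WT. The within-set medians were above 0 in both, the lower at 0.471 in the first set and the other from replicate 3 of each genotype alone. The 14 markers deviated together between mice of the same group, with a mean pairwise correlation of 0.486 (upper limit of the middle 95% of random lists 0.155). Interferon-stimulated and cell cycle genes, with estimated correlations of 0.31 and 0.3, also lay above that limit. The test thus cannot tell B cells or their RNA in varying amounts from other causes of joint deviation. It leaves B cells open as a source in the activated KO samples. A sort for Kb-OVA+ CD8 T cells would remove B cells, and H2-Aa reached 8.02 and Cd79a 6.57 in activated KO cells, while Cd74 was not analysed here. Naive WT samples had Ighm at 10.23 and Cd79b, chosen after its values were seen, at 6.52, so that T cells were not excluded as a source of these 2 of the 14 markers, and a change of the T cells themselves was not tested.

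Genes that differ by genotype in both states were led by Gm7609, the 1 gene called in both (3.77 log2 in naive and 4.60 in activated cells). Chromosome segments that differ between KO and WT mice were tested by genomic neighbours among the 50 genes of smallest p, and 2 such genes had a neighbour in naive cells and 0 in activated cells (random sets 0 to 6 in each). Before the amendment these values argued against segments, and after it they leave segments open, as they do copies of Gm7609 that vary in number between mice, which were not tested. An effect of the knockout itself on Gm7609 may also be the cause and was not tested apart.

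The memory-associated list was called by camera for the interaction, with a median of 0.281 log2 (adjusted p = 0.0165). The call did not hold with an estimated correlation (adjusted p = 0.162), and no cause was tested for it. Among 17824 probe sets without exactly 1 gene name, which the gene comparisons do not use, 2 were called between activated KO and WT cells when all probe sets were tested, at 2.59 and -3.06 log2, and 813 had an unadjusted p under 0.05.

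The same 6 mice can be split into 3 and 3 in 10 ways, the real split included, too few for a share under 0.05. In activated cells the stem-like list had a camera p of 4.23e-14 in the real split and 2.41e-10 at the smallest in the others (1 of 10 splits as small). Genotype calls were 2 genes in naive cells, with 1 the highest in other splits (1 of 10 as many), and 1 gene in activated cells, with 1 the highest in others (3 of 10). List calls were 0 in naive cells, with 1 the highest in others (10 of 10), and 5 in activated cells, with 7 the highest in others (4 of 10). The 10 of 10 was fixed in advance, since no split can call fewer than 0 lists. The 3 other naive splits that part the mice of all 3 replicate numbers called 0 genes and 0 lists. Activation called 1743 genes in WT and 1257 in KO cells, with 1 gene the highest in other splits of each, and 13 and 15 lists, with 8 and 12 the highest (1 of 10 splits as many for each). For the interaction 100 splits of the 12 mice were used, the real one among them. For genes the comparison is empty, since no split can call fewer than the 0 genes of the real split, and the highest was 2. With the real split counted, 52 of the 100 called at least its 3 lists, with 7 the highest, so chance is not excluded for the 3 list calls.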

How the results depend on the processing

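The tests with the array set as a block or each set alone were chosen after seeing the data. Calls of single genes between genotypes changed with the setting, and the cause was not tested except where fewer mice or other numbers of tests enter. In naive cells limma called 2 genes, 1 with the replicate block, only the groups compared, the second technical array or all probe sets, and 0 with quantile normalization, median centring, the first technical array, within the first set, or without any 1 of the 6 naive mice (0 to 0; with all mice 652 at an unadjusted p under 0.05). In activated cells it called 1 gene, 2 with the replicate block or within the second set, 3 with the set as a block, 4 with all probe sets and 0 with only the groups compared. Leaving out a mouse gave 0 (without KO activated replicate 2) to 2 (without WT activated replicates 1 or 2 or KO activated replicate 1). The shared genotype call (1) was 0 to 1, 0 without any naive mouse or KO activated replicate 2.

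Activation counts fell within the sets, to 912 and 922 in WT (1743) and 622 within the first set in KO (1257), where fewer mice enter. The shared lower calls (338) were 207 to 318 with a mouse left out, 214 and 207 without KO naive replicates 2 and 3. Leaving out a mouse gave 1296 to 1561 WT and 900 to 1071 KO genes. With the replicate block 2121 WT and 1556 KO genes were called. The block added calls of Klra9 in activated KO minus WT (adjusted p = 0.0112), Lcn2 in WT and Pdcd1 in KO activation, lost that of the WT survival list (adjusted p = 0.0555), and beside the counts above changed no other call of a gene or list that was followed. Matching numbers outside naive cells gave little sign of pairing (activated correlations 0.12, 0.013 and 0.33, WT 0.2, -0.074 and 0.16, KO 0.19, -0.06 and 0.19). As in naive cells, not every mouse was closest to its own number.

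List calls fell with an estimated correlation from 5 to 2 in activated KO minus WT, 13 to 6 and 15 to 9 for activation in WT and KO, and 3 to 0 for the interaction. fry gave 3 and 0 for the first and the last. In activated cells 8 lists were called within the second set, and 3 (without WT activated replicate 3) to 8 (without KO activated replicate 1) with a mouse left out. For the interaction there were 5 with dim genes left out, 8 within the second set and 2 to 6 with a mouse left out: 5 without WT activated replicate 2 or KO activated replicates 1 or 3 and 6 without KO activated replicate 2. The memory-associated interaction was lost within the first set (adjusted p = 0.698) and without WT naive replicate 2, KO naive replicate 3 or WT activated replicate 3. Naive lists (0) were 2 within the first set and 0 to 1 with a mouse left out (1 without KO naive replicate 2).

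Naive-high genes (mean of 3 medians 0.246) gave 0.387 with 100 genes and 0.151 for the list made with WT activated replicate 1. Activated-high genes (-0.154) gave -0.045 with replicate 3, the choice that left WT mice of the first array set only. Ighm, activated minus naive in WT cells, reversed from -1.41 to 0.25 with the mean of its probe sets (adjusted p = 0.55). Of other settings of called single genes, 2508 kept direction and call and 200 lost the call in the same direction, and of uncalled ones 29 gained it. For called lists 435 kept and 51 lost it. A lone sample of a group, within a set, was assumed to vary like the other groups. Signal over background was not tested, since no detection values are used here.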

Other observations

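No test in this part was chosen after its result was seen. Single genes of the H3K9 and heterochromatin list rose from naive to activated cells. Uhrf1, which recruits the maintenance DNA methyltransferase, rose by 4.07 ± 0.24 log2 in WT and 3.81 ± 0.24 in KO cells (SE, n = 3 mice per group), Cbx5, which encodes heterochromatin protein HP1 alpha, by 1.56 ± 0.15 and 1.24 ± 0.15, Dnmt1 by 1.21 ± 0.13 and 1.19 ± 0.13 and the H3K9 methyltransferase gene Ehmt2 by 0.89 ± 0.20 and 1.01 ± 0.20. The WT call of Ehmt2 was lost without WT naive replicate 1 or WT activated replicate 2. These were the 4 of 17 measured members called higher in WT cells, with 1 called lower and 12 not called, and the list did not pass there (median 0.02, camera adjusted p = 0.126). When adjusted over the list alone, 6 rose and 4 fell in WT cells and 5 rose and 1 fell in KO cells. The list's call in KO cells (median 0.26, adjusted p = 0.00129) was lost with an estimated correlation (adjusted p = 0.117).

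Single genes from marker lists of other cells changed in activated CD8 T cell samples of both genotypes. The lysosomal gene Cd68 rose by 2.69 ± 0.41 in WT and 2.11 ± 0.41 in KO samples and the costimulatory receptor gene Icos by 1.25 ± 0.22 and 0.96 ± 0.22, while Tnfrsf4, which encodes OX40, fell by 1.06 ± 0.18 and 0.97 ± 0.18. The KO call of Icos was lost without any 1 of the KO mice except activated replicate 2. Between genotypes Tnfrsf4 was 0.67 ± 0.18 higher in naive and 0.76 ± 0.18 higher in activated KO cells and passed in neither over all genes (adjusted p = 1 and 0.409), but passed in both when adjusted over its list of 7 CD4 T cell markers alone. Zbtb7b, which directs CD4 T cell fate, differed by -0.25 ± 0.19 in activated cells (adjusted p = 1).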
